A study of Homo sapiens with 6 samples.

How the data were processed

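Single-cell RNA sequencing by Smart-seq2, a full-length polyA protocol without molecular identifiers, had been done on the human embryonic stem cell line HES3-MIXL1-GFP during 3D culture. Per the labels, cells were kept in 2D on Matrigel in E8 medium at 5% oxygen (Day0), then seeded at 50000 cells per well in E8 with 5% Matrigel at 21% oxygen, with 10 uM ROCK inhibitor on the first day. Day2 cells were taken after 2 days, and Day5 cells after a change at day 2 to E8 with 100 ng/ml Activin A. About 30 cysts per time point were dissociated with trypsin, and live cells were sorted into 96-well plates. Libraries were amplified with 23 PCR cycles and sequenced as 75 bp single-end reads on a NextSeq instrument.

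The deposited table holds raw read counts for 59412 gene symbols in 654 cells, and the values were checked to be whole numbers. A second table deposited by the authors gives each cell's day, run, plate and class. Per the submitters' processing notes, Trim Galore 0.5.0, HISAT2 and featureCounts 1.6.1 were used with hg38 (GRCh38.p13). The version of HISAT2, the strand setting of the counting, the annotation release and the clustering method are not stated there. Gene positions were taken from GENCODE 29, which holds 94.0% of the symbols and 99.7% of the reads. Only symbols link the tables, so a gene whose name changed between releases has no position.

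Cells with at least 50000 reads and at least 2000 detected genes were kept, 626 of 654. The 6 samples (3 days in 2 runs) held 78, 89, 69, 133, 80 and 177 kept cells (Day0 run 1 and 2, Day2 run 1 and 2, Day5 run 1 and 2). The total reads in them were 20103678, 14985306, 13896837, 25550715, 10128618 and 38531770. Median reads per kept cell were 117576, 157884, 173565, 167304, 103042 and 208330, and median genes 4636, 4592, 4884, 4570, 4450 and 4247. A single cell held 9.50% of the reads of Day0 run 1, and another 12.8% of those of Day5 run 1. The cells lay on 8 plates, each with 1 day and 1 run. Day2 run 2 was on 2 plates (53 and 81 deposited cells), and so was Day5 run 2 (89 and 92).

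Raw counts were summed over the kept cells of each sample, and the 6 sums were the units of every test between days. edgeR 4.0.16 (R 4.3.3) was used with filterByExpr, TMM factors and robust quasi-likelihood fits of all 6 samples, with 14803 genes tested, 3 residual degrees of freedom and a common biological coefficient of variation of 0.507. Adjusted p-values are Benjamini-Hochberg values over all genes tested, two-sided, with a threshold of 0.05, for 3 comparisons. CPM are TMM-normalised counts scaled to a common total of all reads, mitochondrial reads included. A run holds 1 sample of each day, so a fit with the run as a block (2 residual degrees of freedom) was an alternative. Deviations of run 1 from the mean of each day correlated across genes at -0.03, 0.07 and 0.16 between days. For a gene with 0 reads in a day, the fold is given as at least the ratio of the other day to a floor of 3 reads over the group. For 1 to 3 reads, the ratio is given with its 95% counting interval.

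Gene lists, the genes to be named, the comparisons and most alternatives were fixed before the data were examined. The 36 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Endothelium and blood genes (3 tested, 0 higher and 1 lower from Day2 to Day5) and HOX genes had too few members. Named genes were the 8 higher and 8 lower genes with the largest log2 fold change past the threshold, with at least 50 CPM in the higher day and the same direction in both runs. To these were added up to 4 members with the smallest p of each called list or list with at least 3 changed members, 18 genes chosen in advance, and 5 genes for each pattern of opposite change at both steps. Clone-like names, LINC, MIR and small RNA names, antisense and similar suffixes, XIST, TSIX and genes of chromosome Y were left out of the first and last groups. So were names of genes not annotated as coding that end in P and a number, as pseudogenes often do. HLA-DPB2, a transcribed pseudogene with another kind of name, stayed in. Coding genes whose names end in P and a number (SPP1, SFRP1, BNIP3 and TIMP4) were at first left out by mistake, and were restored to these groups after their values were seen. Genes given only to complete a count of list members were added after their values were seen.

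The test was checked on simulated data, in which read counts of known genes were multiplied in 1 of the days. It recovered 4%, 32%, 86% and 94% of genes at 2-, 4-, 8- and 16-fold between Day0 and Day2, 0%, 40%, 90% and 98% between Day2 and Day5, and 4%, 46%, 88% and 100% between Day0 and Day5. A gene that did not pass may therefore still have changed 4-fold. The changed genes were picked above a minimum mean level, so recovery of weaker genes was not checked. False calls were 4.42%, 5.79% and 7.03% of calls, and 0 of 40 unchanged lists were called in each comparison. Each gene was drawn independently and these lists were of random genes, so the check does not cover lists whose members move together.

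A cell was called positive for a gene with at least 3 reads after its reads were thinned to 50000 at random, with exact 95% Clopper-Pearson intervals. The classes of the authors were used as deposited. Clusters of the kept cells were found with scanpy 1.11.5 and leidenalg 0.10.2. List levels in a cell are the mean of log-normalised values of the members after thinning. A comparison of epiblast-like cells between Day2 and Day5 had been planned and was not run, because these classes held 0 cells at Day5.

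Alternatives were stricter cells (at least 200000 reads and 4000 genes, 179 cells), every deposited cell, cells thinned to the same reads, 69 cells per sample, a replicate block, RLE size factors, no low-count filter and no mitochondrial genes. Others were limma on log2 of the mean CPM per cell plus 1, DESeq2 1.42.0, each sample left out in turn, other thresholds for positive cells, and other cluster settings. Other scalings moved the median gene by less than 0.1 on the log2 scale, and limma on mean CPM per cell, which also changes the test and the weight of each cell, moved it by 0.32 (Day5 against Day2) and 0.28 (Day5 against Day0). Groups of 2 samples allow no outlier test and no useful regrouping of samples.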

Results

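The data were single-cell transcriptomes of human embryonic stem cells grown into 3D cysts, sampled in 2D before 3D culture (Day0), after 2 days in 3D (Day2) and on day 5 (Day5). Activin A at 100 ng/ml was added after day 2. Each day had 2 samples, 1 per batch label (run 1 and run 2). Expression is given as the mean ± SD (n = 2 samples) of normalised read counts (CPM, scaled to a common library size) in the summed reads of a sample, and every share of cells is given for each sample. Time, medium and plate changed together between days, so no comparison separates Activin A from the other changes. The labels do not say that the runs were separate cultures, so the p-values measure only the spread between these samples.

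The 6 sums held 10128618 to 38531770 reads from 69 to 177 cells each. Mitochondrial transcripts took 56.4% of all reads, and MT-RNR2 alone took 46.8%. Their share of a sample's sum was 62.0% and 55.3% at Day0, 64.2% and 59.3% at Day2, and 48.4% and 51.6% at Day5 (run 1, then run 2). Principal components were taken over only those genes that varied most between the sums. The first carried 81.0% of the variance of these genes and set Day5 apart. The second carried 9.09% and set Day0 apart from Day2. Across genes, the Pearson correlation of log CPM was 0.911 between the Day0 samples, 0.912 between the Day2 samples and 0.916 between the Day5 samples. It was 0.871 to 0.908 between Day0 and Day2 samples and 0.724 to 0.780 between Day5 samples and the others.

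During the first 2 days in 3D, NODAL, EOMES, TBXT and MIXL1 rose from very low levels, with few of the other genes of their lists. NODAL (chromosome 10, 70432315 to 70447951, minus strand) rose from 4.3 ± 1.58 CPM at Day0 to 41.2 ± 5.9 CPM at Day2. EOMES (chromosome 3, 27715949 to 27722711, minus strand) had 2 reads in all of Day0 and 4.97 ± 3.01 CPM at Day2, a ratio of 66.4 (counting interval 18.1 to 553). TBXT had 0 reads at Day0 and was at least 78.4-fold higher at Day2, at 9.0 ± 6.21 CPM. By the threshold for positive cells given above, TBXT was positive in only 3 of 69 Day2 cells in run 1 and 5 of 133 in run 2. EOMES was also positive in few Day2 cells, with the shares given below. For TBXT and EOMES the rise in summed reads was therefore not shown for most cells, although cells under the threshold can hold some reads. MIXL1 rose from 0.551 ± 0.599 to 14.8 ± 12 CPM. POU5F1, at 41.3 ± 5.09 CPM at Day0 and 78.4 ± 17.4 CPM at Day2, did not pass the test, and neither did CDH1, at 38.9 ± 2.44 and 36.9 ± 3.13 CPM. In edgeR the log2 fold change of NODAL was 3.26 (SE 0.55, adjusted p = 0.00278), with 2.96 in run 1 and 3.35 in run 2. With the stricter cell filter, which kept 179 cells, NODAL Day2 vs Day0 (2.05, adjusted p = 0.752), EOMES and TBXT no longer passed, while MIXL1 did. The intervals and floors in all comparisons cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

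From Day0 to Day2, 59 of 14803 genes passed an adjusted p of 0.05 in edgeR, 39 higher and 20 lower, and all 59 moved the same way in both runs. The unadjusted p was below 0.05 for 1448 genes. With the run as a block 92 genes passed, 58 higher and 34 lower, and without a low-count filter 120 passed. The count was 104 without Day0 run 2, 96 without Day2 run 2, and 188 and 176 without Day5 run 1 and run 2. The balance of higher and lower genes depended on the setting, with 38 higher and 66 lower without Day0 run 2, 97 and 87 in DESeq2, 96 and 92 without Day5 run 1, and 3 and 4 with stricter cells. Genes of at least 50 CPM in the higher day were ranked only where their names were not left out. Among them ERVH48-1 rose most, from 2.51 ± 0.237 to 112 ± 7.07 CPM (log2 fold change 5.48, SE 0.58, adjusted p = 1.25e-05). NTS rose from 28.3 ± 1.5 to 313 ± 117 CPM and CAV1 from 14.4 ± 5.57 to 79.4 ± 25.3 CPM, though the call for CAV1 Day2 vs Day0 was lost with RLE size factors (adjusted p = 0.0515). NPTX1 was at 52 ± 31.3 CPM at Day0 and had 0 reads at Day2, at least 636-fold lower. SFRP1 fell from 497 ± 227 to 15.1 ± 1.18 CPM. LDHA fell from 3452 ± 1234 to 674 ± 169.8 CPM (adjusted p = 0.0112), and BNIP3 fell from 169.8 ± 36.6 to 26.2 ± 0.073 CPM. WNT3, with 0 reads at Day0, was at least 40.0-fold higher, and GATA3 and HEY1, also with 0 reads at Day0, were at least 32.9-fold and 30.4-fold higher. SMAD7 rose from 0.481 ± 0.129 to 10.8 ± 0.659 CPM and PRDM1 from 0.127 ± 0.18 to 2.97 ± 1.69 CPM. NANOG, SOX2, EPCAM, VIM, CDH2, LEFTY1, LEFTY2 and CER1 did not pass the test. For NANOG the log2 fold change was 1.86 (SE 0.55, adjusted p = 0.176) and for EPCAM -1.02 (SE 0.49, adjusted p = 0.498). GSC had 0 reads on both days, and SNAI1 had too few reads to be tested. ERVH48-1, NANOG and POU5F1 have closely related copies in the genome, so their reads may be shared with those.

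Of 36 gene lists written before the data were examined, camera with a preset correlation called 14 between Day0 and Day2, 12 higher and 2 lower. With an estimated correlation it called 0 (lowest adjusted p = 0.203), and fry, which asks whether a list moves on balance 1 way, called 0 (lowest adjusted p = 0.105). The preset call was 6 lists without Day0 run 2 and 9 without Day2 run 2, in both cases with no list lower. In the primitive streak list, 5 of 14 measured genes rose and 0 fell over all genes tested, and 9 rose adjusted over the list alone (camera adjusted p = 1.25e-08, 0.203 with an estimated correlation). Among 28 Nodal, Activin and TGF-beta targets 5 rose, and 11 rose adjusted over the list alone (5.26e-08). Of 18 BMP targets and antagonists 2 rose, or 9 adjusted over the list alone (4.07e-05). WNT targets had 2 of 17 genes higher, TBXT and WNT3, or 7 higher and 2 lower adjusted over the list alone (0.00363). Both are also in the primitive streak list, as are EOMES, MIXL1 and NODAL of the Nodal targets. GATA3 is in the BMP, amnion and trophoblast lists, so the calls of lists that share genes are not independent. No p53 target of 21 passed over all genes, and 7 rose adjusted over the list alone (3.67e-08), PHLDA3, FAS, MDM2, ZMAT3, BTG2, SESN1 and TNFRSF10B. The other higher lists were amnion and surface ectoderm (2 of 8 rose, 0.000824), FGF and ERK targets (0 of 26, 0.00157), naive pluripotency (0 of 7, 0.00169), nascent and lateral mesoderm (0 of 13, 0.00401), trophoblast (1 of 5, 0.011), core pluripotency (0 of 21, 0.0135) and cholesterol synthesis (0 of 23, 0.0168). The lower lists were amino acid and unfolded protein stress (0 of 18 fell, 0.0113) and hypoxia and HIF targets (1 of 28 fell, 0.0264). Neither was called lower with stricter cells, without Day0 run 2 or without Day2 run 2. Between Day0 and Day2 the definitive endoderm list (median log2 fold change 0, mean 0.29) and the epithelial list (median -0.03, mean 0.16) leaned higher in camera and were not called.

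**Figure D1:**
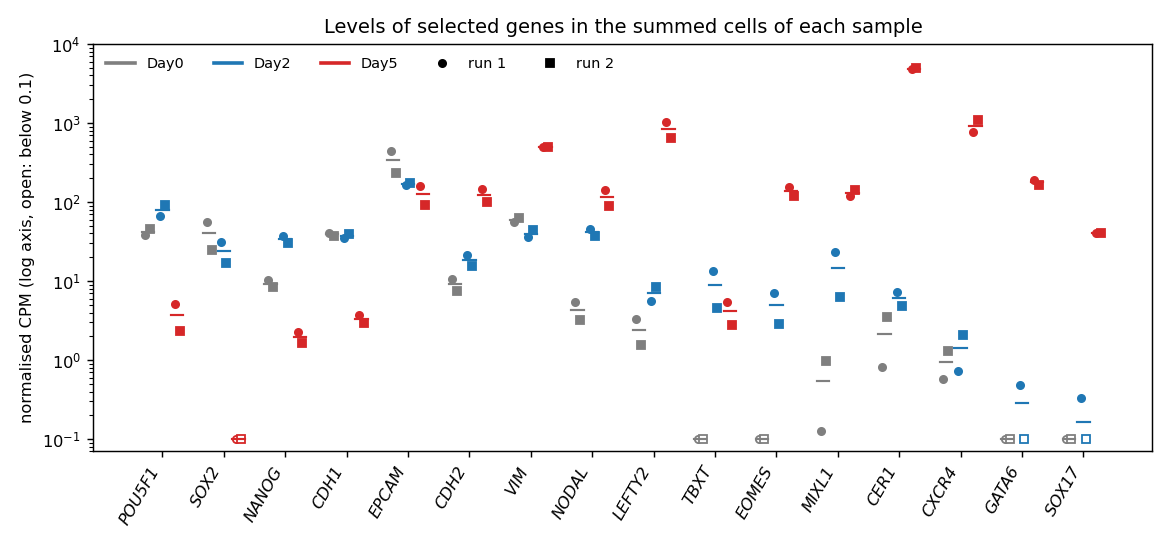
Normalised CPM on a log axis for 16 genes in each of the 6 samples, with circles for run 1, squares for run 2, bars for the mean of a day, and open symbols for values below 0.1. CER1 reached a mean of 4845 CPM at Day5, while SOX2 went from 24 CPM at Day2 to 0 reads at Day5.

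Between Day2 and Day5, with Activin A in the medium, 20 of 26 definitive endoderm genes rose and 11 of 21 core pluripotency genes fell. CER1 (chromosome 9, 14719724 to 14722717, minus strand), a secreted Nodal antagonist, rose from 6.06 ± 1.82 to 4845 ± 73.7 CPM. CXCR4 rose from 1.42 ± 0.966 to 927 ± 228 CPM and GATA6 from 0.286 ± 0.288 to 179 ± 18.3 CPM. SOX17 (chromosome 8, 54457935 to 54460888, plus strand) rose from 0.163 ± 0.231 to 40.7 ± 0.151 CPM. FOXA2 had 0 reads at Day2 and 11.6 ± 0.60 CPM at Day5, at least 139-fold higher. In the opposite direction SOX2 (chromosome 3, 181711924 to 181714436, plus strand) went from 24 ± 10.0 CPM to 0 reads, at least 404-fold lower. POU5F1 (chromosome 6, 31164337 to 31180731, minus strand) fell from 78.4 ± 17.4 to 3.74 ± 1.98 CPM and NANOG from 33.8 ± 4.87 to 1.96 ± 0.455 CPM. For CER1 the edgeR log2 fold change was 9.65 (SE 0.72, adjusted p = 4.95e-09), and for POU5F1 -4.41 (SE 0.60, adjusted p = 1.33e-05).

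From Day2 to Day5, 1637 genes changed in edgeR, 914 higher and 723 lower, and 1636 of them moved the same way in both runs. Of these, 1471 changed over 4-fold, and 3468 genes had an unadjusted p below 0.05. RLE size factors gave 928 higher and 692 lower, and leaving out mitochondrial genes 940 and 688. Stricter cells, with 5 cells left in Day5 run 1, gave only 279 higher and 170 lower. limma on log2 of the mean CPM per cell, which changes the test and the weight of each cell as well as the scaling, placed the median gene 0.32 higher and called 1898 higher and 550 lower. Genes of at least 50 CPM in the higher day were again ranked only where their names were not left out. Those that rose most from 0 reads were GYPB (at least 3324-fold, to 254 ± 53.6 CPM), GYPE (at least 1425-fold), PRSS2 (at least 1069-fold) and RBM24 (at least 524-fold). GYPB with GYPE, and PRSS2 with PRSS1, have near copies, so their reads may be shared. ERBB4 had 2 reads at Day2 and 319 ± 93.3 CPM at Day5, a ratio of 5212 (counting interval 1442 to 43038). MYL4 and LHX1 had 1 read each at Day2 and reached 78.9 ± 11.7 and 55.9 ± 28.4 CPM, and NPPB rose from 0.245 ± 0.347 to 206 ± 74.1 CPM. On the lower side, LNCPRESS1 fell from 168 ± 25.8 to 0.0592 ± 0.0837 CPM, CNMD from 96.6 ± 18.3 to 0.863 ± 0.651 CPM and POLR3G from 110.2 ± 39.4 to 1.36 ± 1.09 CPM. VSNL1 had 138 ± 48.9 CPM at Day2 and 2 reads at Day5. SPP1, PROM1, HLA-DPB2 (a transcribed pseudogene) and MT1G completed the 8 ranked genes of at least 50 CPM that fell most, each from above 50 CPM to at most 1.02 CPM.

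Genes of the definitive endoderm list rose at 20 of 26 measured members and fell at 1, APELA, which went from 32.3 ± 4.69 CPM to 0 reads, at least 622-fold lower. Adjusted over the list alone 23 rose and 2 fell (camera adjusted p = 8.17e-16, 0.293 with an estimated correlation). Within the primitive streak list 8 of 14 rose, or 9 with 1 lower adjusted over the list alone (1.59e-05, 0.310 with an estimated correlation). GSC, FGF17 and DKK4 had 0 reads at Day2 and were at least 209.9-fold, 521-fold and 259-fold higher at Day5. EOMES rose from 4.97 ± 3.01 to 137 ± 22.6 CPM and MIXL1 from 14.8 ± 12 to 132 ± 17 CPM. TBXT, at 9.0 ± 6.21 CPM at Day2 and 4.13 ± 1.95 CPM at Day5, did not pass the test (adjusted p = 0.397). Axial mesoderm and node genes rose at 4 of 7 members and fell at 1 (0.00103, estimated 0.310), with FLRT3 at 63.3 ± 8.68 CPM and NOG at 15.5 ± 8.0 CPM at Day5. This list shares GSC, FOXA2 and TBXT with the primitive streak list and FOXA2 with the definitive endoderm list, so its call is not independent of theirs. The extraembryonic endoderm list, which shares GATA4, SOX17 and HNF4A with the definitive endoderm list, rose at 6 of 12 and fell at 1 (0.000323, estimated 0.306). Its APOA2 had 2 reads at Day2 and 58 ± 15.3 CPM at Day5, a ratio of 1161 (counting interval 321 to 9587). Nascent and lateral mesoderm rose at 4 of 13 members, HAND1, APLNR, BMP4 and RSPO3, and was not called as a list (0.0664). Core pluripotency fell at 11 of 21 and rose at 0 (1.54e-07, estimated 0.306), and ESRG in it fell from 331 ± 12.4 to 10.9 ± 0.752 CPM. The primed and formative epiblast list was split, with 5 of 18 higher and 6 lower. OTX2 rose from 28.2 ± 13.8 to 634 ± 17.1 CPM and SFRP1 from 15.1 ± 1.18 to 426 ± 168 CPM, while SFRP2 and USP44 fell.

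From Day2 to Day5 CDH1 fell, CDH2 and VIM rose, and EPCAM did not pass the test. CDH1 (E-cadherin, chromosome 16, 68737225 to 68835548, plus strand) fell from 36.9 ± 3.13 to 3.34 ± 0.573 CPM. CDH2 (N-cadherin, chromosome 18, 27950966 to 28177446, minus strand) rose from 18.5 ± 4.15 to 122 ± 32.6 CPM. VIM (chromosome 10, 17228259 to 17237593, plus strand) rose from 39.8 ± 5.84 to 498 ± 4.06 CPM. EPCAM (chromosome 2, 47345158 to 47387601, plus strand) was at 168 ± 5.47 CPM at Day2 and 126 ± 49.1 CPM at Day5. In edgeR the log2 fold change was -3.47 for CDH1 (SE 0.56, adjusted p = 0.000112, -3.05 in run 1 and -3.53 in run 2) and 2.72 for CDH2 (SE 0.53, adjusted p = 0.000991, 2.73 and 2.63). For EPCAM it was -0.42 (SE 0.48, adjusted p = 0.693, -0.04 and -0.92), and with the stricter cell filter EPCAM Day5 vs Day2 was 0.39. With that filter CDH1 Day5 vs Day2 fell by 2.5 on the log2 scale and no longer passed (adjusted p = 0.123), while CDH2 and VIM still did, but it left Day5 run 1 with 5 cells, of which 1 held 54.2% of the reads.

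The epithelial list fell at 10 of 29 members, CLDN10, MARVELD3, CDH1, CDH3, CLDN4, GRHL2, MAL2, AP1M2, CBLC and ST14, and rose at 2, KRT8 and KRT19 (camera adjusted p = 0.000323, 0.306 with an estimated correlation). Adjusted over the list alone 13 fell and 2 rose. CLDN10 fell from 36.9 ± 12.5 to 1.09 ± 0.298 CPM and CDH3 from 15.6 ± 1.5 to 1.36 ± 0.254 CPM. KRT8 has many processed pseudogenes, so its reads may be shared with them. The mesenchymal list rose at 8 of 30 members and fell at 1 (0.0153, 0.306 with an estimated correlation), or 10 and 2 adjusted over the list alone. COL5A2 rose from 14.1 ± 3.74 to 326 ± 17 CPM and CDH11 from 0.616 ± 0.294 to 10.2 ± 2.18 CPM. Apical polarity and lumen genes went both ways, with 3 of 31 higher and 3 lower, among them PROM1 and SHROOM3 on the lower side. Integrins and focal adhesion had 2 of 24 higher and 3 lower, with ITGA5 at 1.65 ± 2.05 CPM at Day2 and 20.7 ± 4.65 CPM at Day5 and ITGA6 at 35.2 ± 4.74 and 2.51 ± 0.332 CPM. None of these last 2 lists was called.

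Genes of signalling pathways went both ways from Day2 to Day5. LEFTY2 rose from 7.02 ± 1.96 to 842 ± 278 CPM and LEFTY1 from 22.9 ± 4.66 to 155 ± 47.8 CPM (log2 fold change 2.75, SE 0.52, adjusted p = 0.000786). NODAL was at 41.2 ± 5.9 CPM at Day2 and 115 ± 36.3 CPM at Day5 and did not pass the test (adjusted p = 0.0649). BMP2 rose from 0.431 ± 0.264 to 41.4 ± 7.79 CPM and BMP4 from 4.92 ± 0.146 to 28.5 ± 2.44 CPM, while ID1, a BMP target, fell from 174 ± 23.2 to 13.3 ± 6.72 CPM. LGR5 had 0 reads at Day2 and was at least 279-fold higher, and DKK1 rose from 0.287 ± 0.172 to 32.4 ± 10.9 CPM. Nodal, Activin and TGF-beta targets rose at 12 of 28 and fell at 3, or 14 and 5 adjusted over the list alone (camera adjusted p = 0.0109, 0.463 with an estimated correlation). WNT targets rose at 6 of 17 and fell at 1, or 8 and 2 adjusted over the list alone (0.0375, 0.306 with an estimated correlation). FGF and ERK targets (5 of 26 higher, 4 lower), BMP targets and antagonists (5 of 18 higher, 3 lower) and YAP and TEAD targets (4 of 20 higher, 3 lower) were split and not called. Nodal, Activin and TGF-beta ligands, receptors and SMADs rose at 2 of 19 and were not called (0.163).

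Hypoxia targets had 4 of 28 genes higher and 1 lower at Day5 than at Day2, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00624, 0.306 with an estimated correlation). BNIP3 rose from 26.2 ± 0.073 to 269.9 ± 32.5 CPM, SLC2A3 from 158 ± 25.7 to 1003 ± 47 CPM and MXI1 from 2.05 ± 1.06 to 24 ± 9.39 CPM, whereas SLC2A1 fell from 47.1 ± 24.9 to 12.7 ± 2.92 CPM. Of 20 glycolysis genes 2 rose and 2 fell, and LDHA among them rose from 674 ± 169.8 to 2137 ± 33 CPM. Amino acid and unfolded protein stress genes rose at 6 of 18 and fell at 1 (0.0083, estimated 0.310), with ATF3 rising from 1.48 ± 0.00902 to 31.5 ± 11.3 CPM and HSP90B1 from 365 ± 54.7 to 1213 ± 238 CPM. S phase genes fell at 7 of 44 and rose at 0 (0.000323), and G2 and M phase genes fell at 2 of 51 and rose at 0, or fell at 0 adjusted over the list alone (0.00666), both 0.306 with an estimated correlation. HELLS fell from 219.5 ± 42.5 to 37.7 ± 13 CPM and MCM4 from 46.6 ± 0.0234 to 11.9 ± 0.181 CPM. Across the 36 lists camera called 13 between Day2 and Day5, 9 higher and 4 lower, an estimated correlation left 0 (lowest adjusted p = 0.293), and fry called 9, all among the 13. Of the 13, fry did not call amino acid and unfolded protein stress (fry adjusted p = 0.0547) or S phase (0.0553). Nor did fry call G2 and M phase or WNT targets (both 0.0587). Oxidative phosphorylation (36 measured), mitochondrially encoded (13) and cholesterol synthesis (23) genes had 0 members past the test. The lists for FGF and ERK targets (median log2 fold change -0.51, mean 0.15) and cholesterol synthesis (median 0.10, mean 0.02) leaned lower in camera despite a positive mean.

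**Figure D2:**
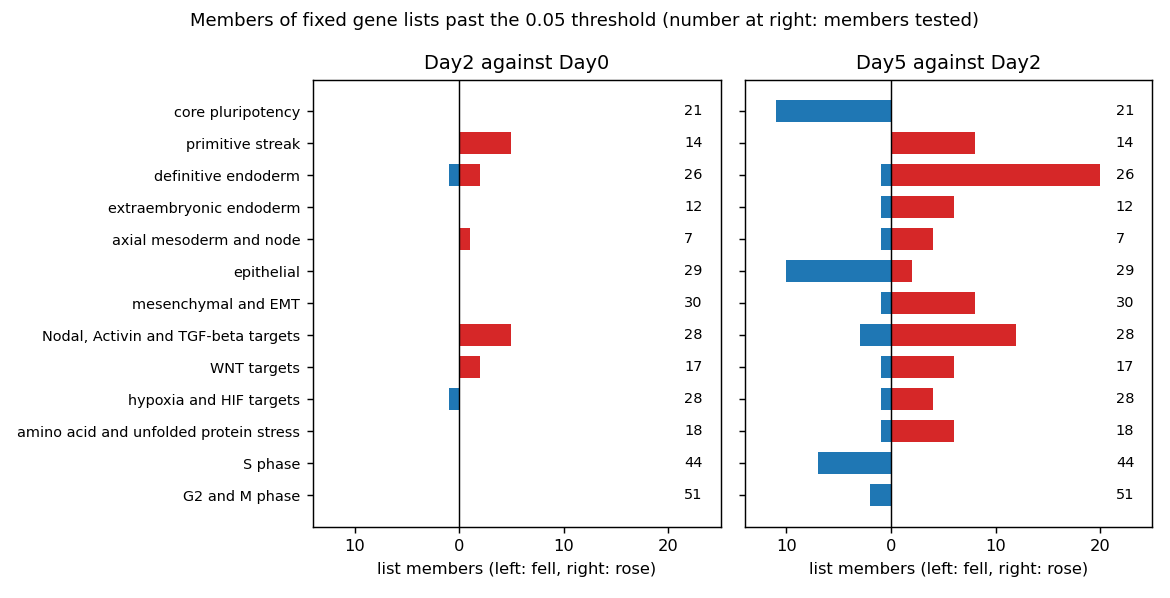
Number of measured genes of 13 lists that rose or fell past an adjusted p of 0.05 in edgeR, from Day0 to Day2 and from Day2 to Day5. At the second step 20 of 26 definitive endoderm genes rose and 11 of 21 core pluripotency genes fell.

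Over the whole course from Day0 to Day5, 21 of 26 definitive endoderm genes rose, and CDH1 and CDH2 moved in opposite directions. CDH2 rose from 9.05 ± 2.14 to 122 ± 32.6 CPM and VIM from 59.5 ± 4.26 to 498 ± 4.06 CPM, while CDH1 fell from 38.9 ± 2.44 to 3.34 ± 0.573 CPM. ZEB1 had 0 reads at Day0 and 4.2 ± 0.326 CPM at Day5, at least 44.8-fold higher. TBXT, with 0 reads at Day0, was at least 35.5-fold higher at Day5, and NODAL rose from 4.3 ± 1.58 to 115 ± 36.3 CPM. EPCAM, at 341 ± 148 CPM at Day0 and 126 ± 49.1 CPM at Day5, was just short of the threshold (log2 fold change -1.44, SE 0.49, adjusted p = 0.0517). The edgeR log2 fold change of CDH2 was 3.75 (SE 0.55, adjusted p = 3.66e-05).

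From Day0 to Day5, 2052 genes changed in edgeR, 1108 higher and 944 lower. Of these, 2048 moved the same way in both runs, 1804 changed over 4-fold, and 3966 genes had an unadjusted p below 0.05. The count was 1217 without Day0 run 1 and 1330 without Day5 run 1. limma on the mean CPM per cell placed the median gene 0.28 higher and called 1857 higher and 695 lower. Stricter cells left 587 changed genes, 346 higher and 241 lower. NPPB, GYPE, PRSS2 and LHX1 had 0 reads at Day0 and rose by at least 472-fold each, and GRP had 1 read at Day0 and 106 ± 46.8 CPM at Day5. PTPRZ1 fell from 65.8 ± 31.7 to 0.142 ± 0.201 CPM, PSAT1 from 807 ± 336 to 109 ± 9.56 CPM and PMAIP1 from 121 ± 76.9 to 3.88 ± 3.14 CPM. TERF1 fell from 449 ± 85.5 to 52 ± 11 CPM, and NANOG from 9.28 ± 1.28 to 1.96 ± 0.455 CPM (adjusted p = 0.00839). FST rose from 11.6 ± 0.803 to 145 ± 39.2 CPM and GDF3 from 26 ± 14.5 to 98.1 ± 23.6 CPM. Only 3 HOX genes had enough reads to be tested, HOXB2, HOXB3 and HOXB7, and all 3 rose from 0 reads, by at least 12.4-fold, 13.7-fold and 19.7-fold. In the basement membrane list 2 of 23 rose, LAMB1 and EGFLAM, and 3 fell, FREM2, LAMA3 and NID1, or 6 and 3 adjusted over the list alone, and the list was not called.

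Camera called 15 of the 36 lists between Day0 and Day5, 11 higher and 4 lower. An estimated correlation left 0 (lowest adjusted p = 0.194), and fry called 18, including all 15. Higher lists were definitive endoderm (21 of 26 rose and 1 fell, camera adjusted p = 8.38e-15), primitive streak (12 of 14 rose, 0 fell, 5.4e-14), Nodal, Activin and TGF-beta targets (16 of 28 rose, 2 fell, 4.91e-06), extraembryonic endoderm (6 of 12 rose, 1 fell, 1.39e-05), axial mesoderm and node (6 of 7 rose, 1 fell, 2.25e-05) and WNT targets (8 of 17 rose, 0 fell, 2.67e-05). Nascent and lateral mesoderm (5 of 13 rose, 0 fell, 0.000469), BMP targets and antagonists (9 of 18 rose, 2 fell, 0.0019), the mesenchymal list (10 of 30 rose, 1 fell, 0.00302), trophoblast (2 of 5 rose, 0 fell, 0.0215) and p53 targets (2 of 21 rose, 1 fell, 0.046) were also higher. The p53 call was lost with a replicate block (0.0525). Lower lists were S phase (6 of 44 fell, 0 rose, 1.39e-05), core pluripotency (10 of 21 fell, 1 rose, 0.000133), G2 and M phase (6 of 51 fell, 1 rose, 0.00114) and epithelial (10 of 29 fell, 3 rose, 0.00128). The primordial germ cell list (median log2 fold change -1.48, mean 0.07), NOTCH targets (0.71, 0.22) and oxidative phosphorylation (0.13, 0.01) leaned lower in camera against the sign of their mean and were not called.

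Both steps together gave 9 genes that rose from Day0 to Day2 and rose again to Day5, against 2.41 if the steps' calls were independent. These included EOMES, MIXL1, PRDM1, BMPER, HAS2, ENC1 and WLS. Another 13 rose and then fell (1.90 if independent), among them CAV1, HEY1, HPGD, HHLA1, GLIPR1L1 and TIMP4. HHLA1 was at 1.06, 17.3 and 0.0959 CPM at Day0, Day2 and Day5. A further 10 fell and then rose (1.23 if independent), BNIP3, LDHA, LRIG1, P3H2, PDZRN3, RCAN2, SFRP1, SLC1A1, SOX21 and STC1. STC1 was at 32.7, 2.65 and 243 CPM, and SLC1A1 had 12.2 CPM, then 2 reads, then 15.3 CPM. Between Day0 and Day5, SLC1A1 (log2 fold change 0.32, adjusted p = 0.80), RCAN2 (-0.58, adjusted p = 0.677) and SFRP1 (-0.22, adjusted p = 0.821) did not pass the test. The log2 fold change of SLC1A1 Day5 vs Day0 was -0.14 without Day0 run 2, and that of RCAN2 Day5 vs Day0 was 1.07 without Day0 run 1. No gene fell at both steps (0.977 if independent). The 32 genes changed at both steps became 52 without Day0 run 2, and 67 and 71 without Day5 run 1 and run 2. Because Day2 is in both steps, its sampling error alone pushes genes toward opposite signs. Across genes, the Pearson correlation of the log2 fold changes of the steps was -0.196, against a mean of -0.501 in 50 data sets simulated without any change, and their covariance was -0.640 against -0.377 (SD 0.0114). The simulation gave each gene its mean level over all days, so its Day2 error is not that of the data. These gaps therefore do not measure reversal. The Day2 samples were also divided between the steps, a test chosen after the data were seen. With run 1 for the first step and run 2 for the second, and then the reverse, 25 and 13 genes rose at both steps (2.90 and 2.04 if independent), and 10 and 8 rose and then fell (2.59 and 1.82). Another 7 and 12 fell and then rose (1.04 and 0.833), and 2 and 1 fell at both steps. Across genes the correlation was then -0.0112 and -0.0267 and the covariance -0.0597 and -0.133, so without a shared Day2 sample the steps were nearly uncorrelated. Called genes with opposite changes still exceeded the numbers if independent, but so did genes that rose at both steps. The numbers if independent, here and above, take every gene as equally likely to be called. An excess over them therefore does not by itself show reversal. With run 1 for the first step more genes rose at both steps than changed in opposite directions.

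Expression was also measured as the share of positive cells, defined as at least 3 reads after each cell was thinned to 50000 reads. Of Day5 cells in run 1 and run 2, 97.5% and 98.9% were CER1-positive (exact 95% intervals 91.3 to 99.7 and 96 to 99.9), against 1.45% and 4.51% at Day2. EOMES-positive cells made up 81.2% and 67.2% of Day5 (71 to 89.1 and 59.8 to 74.1) and 2.9% and 3.76% of Day2. SOX17-positive cells made up 37.5% and 29.4% of Day5 (26.9 to 49 and 22.8 to 36.7), and FOXA2-positive cells 13.8% and 8.47% (7.07 to 23.3 and 4.82 to 13.6). CDH2-positive cells were 13% and 12% of Day2 and 75% and 58.8% of Day5 (64.1 to 84 and 51.1 to 66.1). CDH1-positive cells went from 26.1% and 13.5% to 3.75% and 3.39% (0.78 to 10.6 and 1.25 to 7.23). EPCAM-positive cells went from 84.1% and 75.9% to 41.2% and 42.4% (30.4 to 52.8 and 35 to 50), although the summed level of EPCAM did not pass the test. POU5F1-positive cells went from 36.2% and 51.9% to 2.5% and 2.82% (0.304 to 8.74 and 0.923 to 6.47). SOX2 was positive in 0 of 80 and 0 of 177 Day5 cells, with exact 95% intervals of 0 to 4.51 and 0 to 2.06. NODAL-positive cells were 2.56% and 1.12% of Day0, 33.3% and 25.6% of Day2 (22.4 to 45.7 and 18.4 to 33.8) and 65% and 58.2% of Day5. TBXT-positive cells stayed at or below 8.75% in every sample. For 21 of 26 genes both Day5 samples lay on the same side of both Day2 samples, which chance gives with a probability of 0.333 per gene. That is also the smallest p a two-sided exact permutation test of 2 against 2 samples can give. A fixed total of reads held more nuclear reads at Day5, because the mitochondrial share was lower there.

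**Figure D3:**
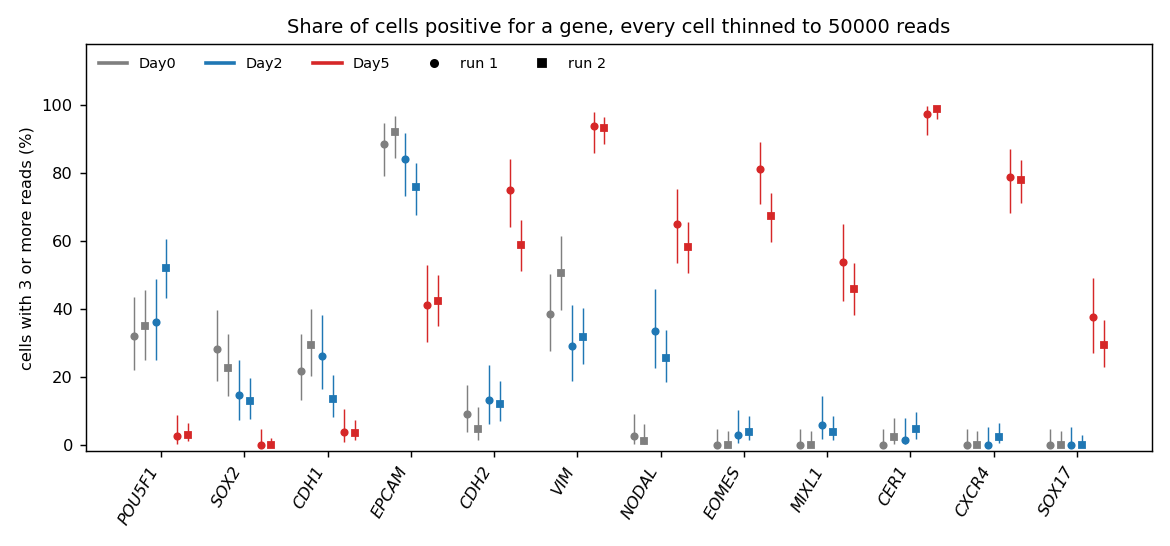
Percentage of cells positive (at least 3 reads after thinning to 50000) for 12 genes in each of the 6 samples, with exact 95% intervals. CER1 was positive in 97.5% and 98.9% of Day5 cells and SOX2 in 0 of them.

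Cells positive for both CDH1 and CDH2 were 2 of 80 and 5 of 177 at Day5, against 2.25 and 3.53 if the genes were independent in each sample. SOX17 and FOXA2 were both positive in 7 of 80 and 8 of 177 cells (4.12 and 4.41 if independent). TBXT and SOX17 were both positive in 0 of 80 and 1 of 177 cells (2.62 and 1.18 if independent), and SOX2 and SOX17 in 0 of either. These differences from independence were not tested. Over single cells of a sample, the Spearman rho between the mean level of the epithelial list and that of the mesenchymal list was 0.53 and 0.34 at Day0, 0.39 and 0.42 at Day2, and 0.06 and 0.36 at Day5. Between core pluripotency and definitive endoderm it was 0.18 and 0.25, 0.48 and 0.38, and 0.61 and 0.50. These levels were taken at a fixed total of reads, mitochondrial reads included. A cell with a lower mitochondrial share can therefore score higher on both lists, so a positive rho does not by itself show expression of both in the same cells. Cells of a sample are not independent replicates.

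The authors assigned each of the 654 cells to 1 of 6 classes, which are named here as deposited. At Day0, 91 of 91 cells of run 1 and 82 of 90 of run 2 were PSCs, and the other 8 were Post.EpiLike 1. At Day2 in run 1, 52 of 71 cells were Post.EpiLike 1 (73.2%, exact 95% interval 61.4 to 83.1) and 19 were Post.EpiLike 2. The 2 plates of Day2 run 2 differed, with 26 of 53 cells (49.1%, 35.1 to 63.2) and 5 of 81 (6.17%, 2.03 to 13.8) in Post.EpiLike 1. At Day5 every cell was in a PS-like class. PS-like 1, 2 and 3 held 22, 36 and 29 of 87 cells in run 1, and 27, 39 and 23 of 89 and 19, 33 and 40 of 92 cells on the plates of run 2. Because every plate held cells of a single day, plate and day cannot be told apart. Clustering of the 626 kept cells gave 5 clusters, which had an adjusted Rand index of 0.661 with the authors' classes. Cluster 0 held 96.2% and 96.6% of Day0 cells, 2 others held all Day5 cells, and 2 held most Day2 cells. With other resolutions the number was 3 to 10.

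**Figure D4:**
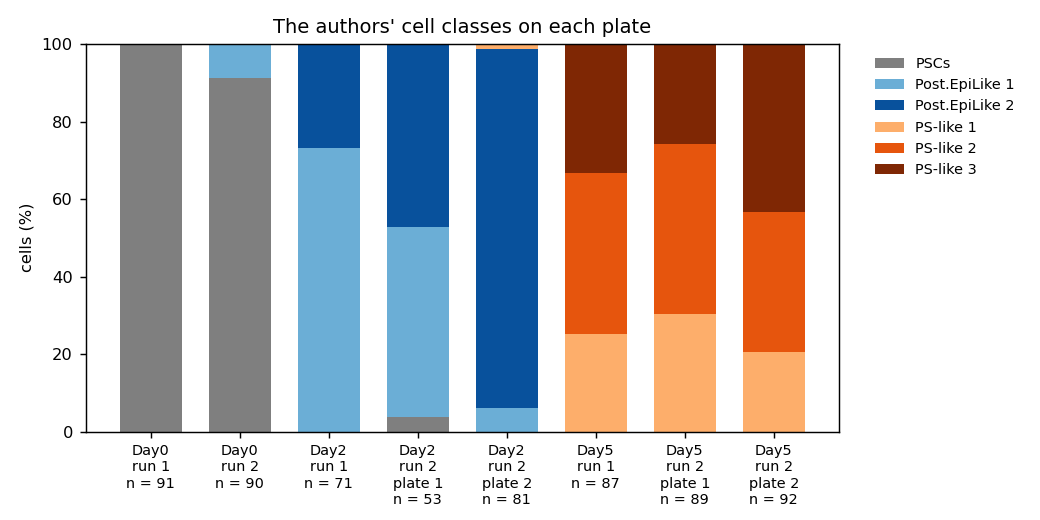
Percentage of the deposited cells of each of the 8 plates in each of the authors' 6 classes, as stacked bars. The plates of Day2 run 2 have 49.1% and 6.17% of cells in Post.EpiLike 1, while all Day5 plates hold only PS-like classes.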

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

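Using a single plate of Day2 run 2 or Day5 run 2, leaving out the deepest cell of each sample, and dividing the Day2 samples between the steps were chosen after the data were seen. The plates and deepest cells left 41 to 74, 1491 to 1723 and 1761 to 2149 changed genes (Day2 against Day0, Day5 against Day2, Day5 against Day0).

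Day2 against Day0 moved most. Its 59 genes became 92 with a replicate block that pairs the runs, 120 without a low-count filter, 184 in DESeq2 and 7 with stricter cells. The 39 higher and 20 lower became 38 and 66 without Day0 run 2, 97 and 87 in DESeq2, and 3 and 4 with stricter cells. Leaving out each sample gave 41 to 188, with 104 without Day0 run 2, 96 without Day2 run 2, and 188 and 176 without Day5 run 1 and run 2. A lone sample was then assumed to vary like the other groups. Stricter cells, which left 179 of 626 cells and 5 in Day5 run 1, lowered Day5 against Day2 from 1637 to 449 and Day5 against Day0 from 2052 to 587. Leaving out each sample gave 1125 to 1821 and 1217 to 2436, with 1217 without Day0 run 1 and 1330 without Day5 run 1. With the block these counts were 1795 and 2213.

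Genes changed at both steps went from 32 to 88 in DESeq2 and to 24 to 71 without a sample (52 without Day0 run 2, 67 and 71 without Day5 run 1 and run 2). Dividing the Day2 samples between the steps gave 44 and 34. The cause was not tested for any of these moves.

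An estimated correlation left 0 called lists in each comparison, where the preset value gave 14, 13 and 15. Between Day0 and Day2 fry called 0 and stricter cells 4, none lower, and leaving out each sample gave 6 to 14 (6 without Day0 run 2, 9 without Day2 run 2, neither with a lower list). The other ranges were 9 to 13 and 14 to 15. Clusters went from 5 to 3 at resolution 0.3 and to 10 at resolution 1.0. Genes with separate Day2 and Day5 shares were 16 to 22 of 26.

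Of the named genes, 25, 109 and 128 were called in the 3 comparisons. Stricter cells ended 18, 33 and 43 of these calls, the replicate block 0, and DESeq2 0, 2 and 2. Signs reversed for genes that had not passed. CDH1 Day2 vs Day0 ranged from -0.18 to 0.029 without a sample, and was 0.25 with the first plate of Day2 run 2 and 0.0076 without the deepest cells. EPCAM Day5 vs Day2 was 0.39 with stricter cells. SLC1A1 Day5 vs Day0 ranged from -0.14 to 1.01 without a sample. RCAN2 Day5 vs Day0 ranged from -1.33 to 1.07 without a sample, and was 0.012 with the block, 0.36 thinned, 0.0070 with equal cell numbers and 0.61 in limma. SFRP1 Day5 vs Day0 ranged from -0.69 to 0.36 without a sample, and was 0.27 with stricter cells and 0.11 in limma. The cause was not tested.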

Other observations

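The tests of oxygen and of long transcripts on the plates, the EPCAM check with thinned nuclear reads, and the genes named in the next paragraph were chosen after the results were seen.

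Among the authors' Day5 classes, several genes differed in the same direction in both runs. Cells positive for EPCAM made up 67.7% and 69.4% of PS-like 2, 38.1% and 48.8% of PS-like 1, and 14.3% and 6.5% of PS-like 3 (run 1, then run 2). Those positive for CXCR4 made up 100% and 98.6% of PS-like 2 but 46.4% and 50% of PS-like 3, and those positive for LEFTY2 90.3% and 90.3% but 17.9% and 19.4%. In the opposite direction, APLNR was positive in 46.4% and 29% of PS-like 3 and in at most 2.8% of the other Day5 classes. Cells positive for FOXA2 were most frequent in PS-like 1, at 42.9% and 16.3%. CDH2 was positive in 100% and 76.4% of PS-like 2, 67.9% and 51.6% of PS-like 3, and 47.6% and 39.5% of PS-like 1. The mean level of FN1 was 150 and 227 CPM in PS-like 2, against 30.0 and 38.7 CPM in PS-like 3. At Day2, cells positive for KRT8 made up 68% and 46.7% of Post.EpiLike 1 and 15.8% and 24.0% of Post.EpiLike 2, and those positive for CDH1 34% and 23.3% against 5.3% and 10.0%. A fixed total of reads held more nuclear reads in PS-like 2 and Post.EpiLike 1, whose median mitochondrial shares were 38.7% and 40.1%, and 60.6% and 43.3%, against 53.3% to 56.8% in the other Day5 classes and 67.2% and 62.4% in Post.EpiLike 2. This favours positive cells there, so part of these differences can come from it. The classes are the authors' division of these same cells, by a method that is not stated, so the differences were not tested.

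The plates of Day2 run 2 were compared over kept cells in either of the authors' Post.EpiLike classes, not over all deposited cells as above. The share in Post.EpiLike 1 was 45.9 percentage points higher on the first plate than on the second. Within terciles of reads per cell the mean difference stayed at 43.3 points (bootstrap interval 28.9 to 56.9), and within terciles of the mitochondrial share at 41.7 points (26.0 to 58.2), which argues against either as the whole cause. Transcript length did not separate the classes in general, since the median log2 ratio of Post.EpiLike 1 to 2 in the longest genes minus that in the shortest was -0.066 in run 1 and 0.95 in run 2. Within Post.EpiLike 2 alone, the first plate exceeded the second by 0.469 more on the log2 scale for the longest than for the shortest genes (0.296 to 0.608, 25 and 75 cells), so a difference between plates in the recovery of long transcripts is a candidate cause. The design names no group that separates these plates, so no biological explanation was tested. The bootstrap intervals cover only the sampling of cells.

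Hypoxia and HIF targets were called lower at Day2 than at Day0 and higher again at Day5 by camera with the preset correlation. With an estimated correlation neither call held (camera adjusted p = 0.211 and 0.306). The lower level at Day2 was not called by fry (adjusted p = 0.109). The lower call was absent with stricter cells and without Day0 run 2 or Day2 run 2. Incubator oxygen was 5% before and 21% after the start of 3D culture, so oxygen alone predicts no rise between Day2 and Day5, yet the list's median log2 fold change was 1.33 (camera adjusted p = 0.00624, fry adjusted p = 0.0288, 4 of 28 genes higher). That argues against incubator oxygen as the whole cause of the second change, and leaves it open for the first. With every cell thinned to the same reads the median was 1.48, which argues against a few deep cells. Lower oxygen inside growing cysts, Activin A and the change of cell state may each contribute and were not tested, and the list was not called with an estimated correlation.

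At Day5 CDH1 fell and CDH2 and VIM rose while EPCAM stayed detectable. A mixture of separate epithelial and mesenchymal cells was taken to predict that EPCAM-positive cells are rarer among CDH2-positive cells by 20 points or more. They were more frequent by 21.7 points in run 1 (bootstrap interval -3.33 to 43.3, Fisher's exact p = 0.118) and 13.8 points in run 2 (-0.711 to 27.8, p = 0.089). With nuclear reads thinned to 20000 the differences were 32.8 (Fisher's exact p = 0.00877) and 14.6 points (p = 0.0641). This does not remove the effect of cell quality, which can move both genes the same way, so the comparison cannot exclude a mixture. By class, EPCAM-positive cells were frequent in PS-like 2 and rare in PS-like 3, although most cells of both were CDH2-positive. The intervals and p-values cover only the sampling of cells within a sample, and cells are not independent replicates. Unequal depth is argued against by the CDH1 log2 fold change of -3.44 (adjusted p = 1.41e-05 in edgeR) with every cell thinned to the same reads, although with stricter cells CDH1 Day5 vs Day2 was -2.5 and lost its call with 179 cells left (adjusted p = 0.123), 5 of them in Day5 run 1, where 1 held 54.2% of the reads. EPCAM was positive in 28 of 60 CDH2-positive Day5 cells in run 1 and in 50 of 104 in run 2. That these cells themselves expressed both genes is a hypothesis that does not extend to protein, and free RNA or cell doublets were not tested.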
